A study of Rattus norvegicus with 12 samples.

How the data were processed

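Messenger RNA was sequenced from coronary arterioles under 150 µm in diameter of female Fischer-344 rats, in 12 libraries. There were 4 libraries from young control rats aged 3 months, 4 from old control rats aged 24 months, and 4 from rats aged 24 months that had received 10000000 adipose-derived stromal vascular fraction (SVF) cells intravenously at 23 months, 4 weeks before the vessels were taken. Per the labels' protocols, each RNA sample held at least 5 microvessels pooled within a group, and libraries were made from polyadenylated RNA with the NuGEN Universal Plus mRNA-Seq kit. Because the vessels of a group were pooled, the p-values given here measure the spread between these RNA samples, and that spread may be partly technical.

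The authors deposited raw counts per gene, 1 column per library. Per the submitters' processing notes, reads were checked with FastQC 0.10.1, mapped to the rat genome build rn6 and counted with HTSeq 0.10.0. The aligner, the annotation release and the strand setting were not given in the sources used here, so overlapping and antisense genes, and close paralogs, may share reads. The table held 24600 gene IDs, of which 8463 had no count in any library. It held no rows other than genes.

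The gene IDs are Ensembl IDs, and neither the table nor the reference gene list pairs them with symbols: 0 of the 24600 IDs could be matched. No gene is therefore named. The tests that need symbols were not run: the 35 gene lists on beta-adrenergic signalling, receptor trafficking, oxidative stress and related topics, the cell type marker indices, the cardiomyocyte marker covariate, and the values of single genes listed beforehand. The rule for naming genes asked for the largest fold changes in each direction among genes with an adjusted p under 0.05, a mean of at least 2 CPM (counts scaled to a common library size), libraries of the 2 groups that do not overlap, and an informative symbol. With no symbols, only 4 IDs are printed. They are the 2 highest rises and the single fall that pass in old control against young control, and the deepest fall that passes in old SVF-treated against young control.

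Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 3 groups (minimum count 10, minimum total 15), which left 12496 genes holding 99.9% of all counts. Library sizes were scaled by TMM. One negative binomial model with the group as the only term was fitted to the 12 libraries, and 3 contrasts were tested with robust quasi-likelihood F tests. P-values were adjusted by the Benjamini-Hochberg method over the 12496 genes within each contrast, and a gene was called at an adjusted p under 0.05. CPM values are TMM-scaled, and a prior count of 2 was added for log2 CPM. Intervals of fold changes are at the 95% level. The common biological coefficient of variation was 37.9%. The comparison of fold changes used 100 simulated sets of 12 libraries with no group effect, and a version in which the 4 old controls were split so that no library entered both fold changes.

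The alternatives tried were DESeq2 1.42.0, RLE size factors, library totals alone, no filter on low counts, a mean CPM of at least 5, a fit of only the 2 groups compared, the replicate number as a block, limma 3.58.1 voom with sample quality weights, a threshold of 0.1, a test against a log2 fold change of 0.5, and leaving out each library. These, the tests of the 3 comparisons and of the covariance, and the naming rule were chosen before the data were examined. Surrogate variables from sva 3.50.0, leaving out the 2 libraries with the lowest rank correlations, and pooling the 8 old libraries were added later, as were the tests that the closing parts name as chosen after the data were seen.

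The tests were checked on simulated data with the real means, library sizes and dispersions of the 12496 genes, in 5 sets with 200 changed genes each. For old control against young control, 10.8% of genes changed 1.5-fold were recovered, 42.0% of those changed 2-fold, 66.0% of those changed 3-fold and 70.8% of those changed 4-fold, and 4.63% of calls were false. For old SVF-treated against old control the shares were 5.20%, 43.6%, 60.8% and 72.0%, and 5.22% of calls were false. For the comparison of fold changes, a simulated full return of 1000 genes with a true covariance of -0.0800 gave -0.0859 by the difference from simulated sets and -0.0716 by split controls. With no effect, the difference averaged -0.00933 over 5 sets (-0.0166 to -0.0047), and split controls gave -0.00336 in 1 set.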

Results

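Gene expression was measured in pooled coronary arterioles of young control, old control and old SVF-treated rats, with 4 libraries per group. The stated aim was to follow changes with age, and after SVF cell injection, in beta-adrenergic vasodilator signalling, receptor handling and oxidative stress. The total count per library ranged from 4068021 to 10821485. It averaged 6346196 ± 2059237 (SD, n = 4) in young controls, 7967581 ± 898508 in old controls and 8058298 ± 1936875 in old SVF-treated rats. The number of gene IDs with at least 1 count ranged from 12320 to 14077, with means of 13101 ± 572 in young controls, 13232 ± 735 in old controls and 13026 ± 656 in old SVF-treated rats (SD, n = 4). The 10 most abundant genes held 6.06% to 8.18% of the counts.

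Libraries differed in how many of the 12496 tested genes had no count. Between 78 and 820 tested genes were at 0, with means of 379 ± 206 in young controls, 382 ± 300 in old controls and 458 ± 301 in old SVF-treated rats (SD, n = 4). The 3 groups did not differ detectably in this number (exact permutation test over 34650 groupings, p = 0.877). The highest number was in old SVF-treated replicate 2 and the lowest in old control replicate 1, which had total counts of 6428823 and 7700079.

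**Figure D1:**
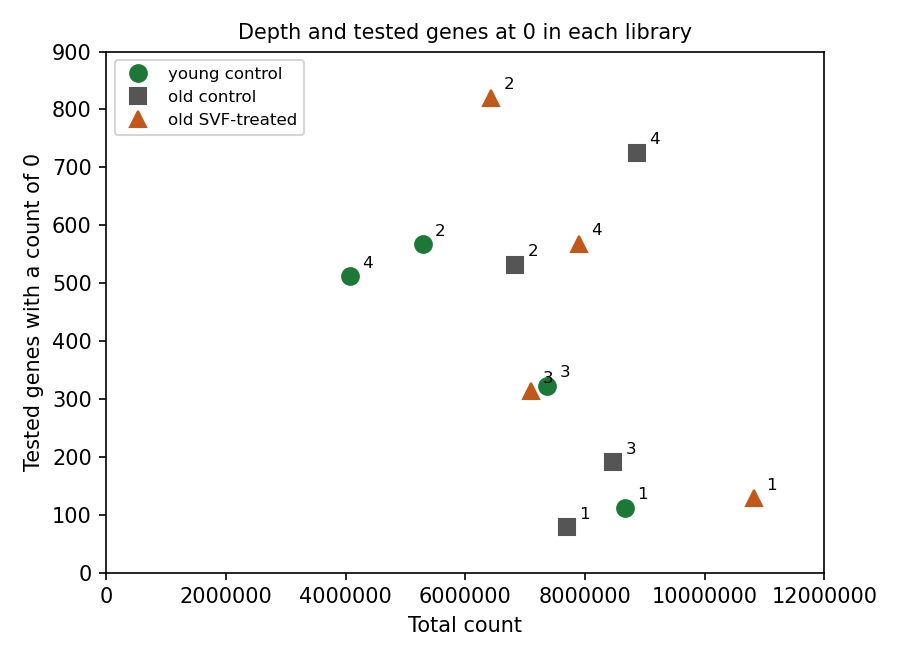
Total count (x axis) against the number of tested genes with a count of 0 (y axis) in each of the 12 libraries, with replicate numbers beside the points. Old control replicate 4 has 725 tested genes at 0 with 8864718 counts, while young control replicate 4 has 512 with 4068021.

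Principal components of log2 CPM did not separate the groups. The first component held 16.4% of the variance, and 83.8% of that came from old SVF-treated replicate 2. The second held 13.8%, of which 79.7% came from old control replicate 4. These 2 libraries also had the lowest median Spearman correlations with the other libraries, 0.939 and 0.945, against a highest value of 0.963. The median share of a gene's variance that lay between groups was 15.7%, and the median that chance gives for 3 groups of 4 is 14.3%.

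**Figure D2:**
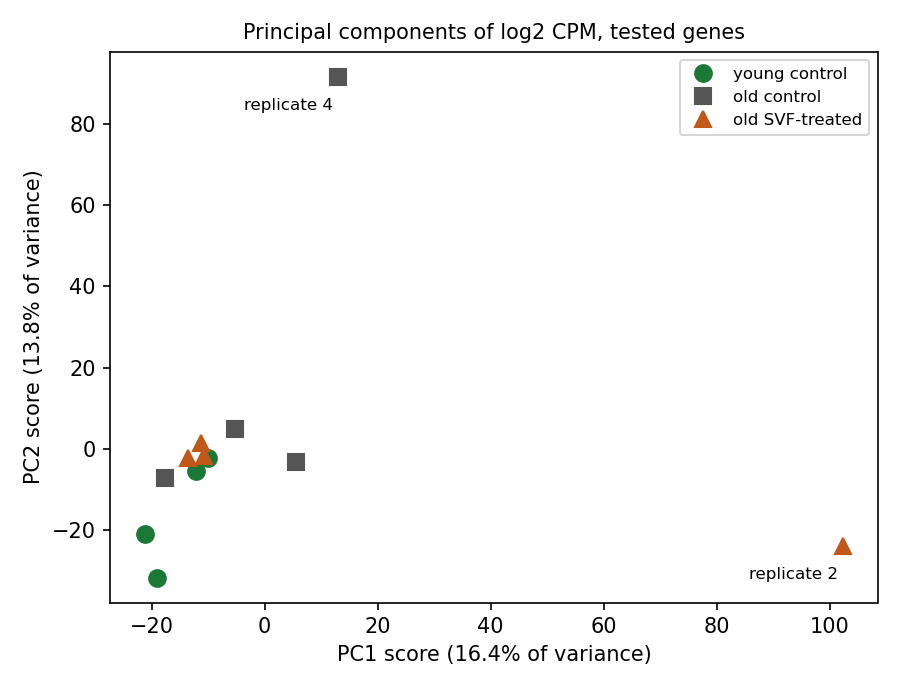
Scores on the first (x axis) and second (y axis) principal components of log2 CPM of the 12496 tested genes, 1 point per library, coloured by group. Old SVF-treated replicate 2 lies alone on the first component and old control replicate 4 lies alone on the second, and the other 10 libraries lie together.

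The effect of age was addressed by comparing old control with young control. Of 12496 genes, 5 were called (edgeR quasi-likelihood test, adjusted p under 0.05), 4 higher and 1 lower in old controls. At an unadjusted p under 0.05 there were 667 genes, and chance gives 625. DESeq2 called 23 genes and limma voom with sample quality weights called 17. The 5 genes changed by 1.00 to 2.74 on the log2 scale, in either direction. The count depended on single libraries: it was 0 without young control replicate 1, 2 without young control replicate 2 or 3, 3 without old control replicate 2, and 12 without old control replicate 1. The split of these 8 libraries that exchanged young control replicate 3 and old control replicate 1 called 86 genes. The 95% interval of a gene's log2 fold change reached a median of 0.59 to either side of the estimate, and 0.35 for the 3087 genes with a mean above 64 CPM.

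The highest rise was in ENSRNOG00000021027, from 16.7 ± 5.78 CPM in young controls to 110 ± 54.8 CPM in old controls (SD, n = 4). This was a log2 fold change of 2.74 (SE 0.40, 95% interval 1.89 to 3.58, edgeR adjusted p = 0.0139). ENSRNOG00000030729 rose from 21.0 ± 9.28 to 69.2 ± 11.2 CPM, a log2 fold change of 1.72 (SE 0.26, 95% interval 1.17 to 2.27, edgeR adjusted p = 0.0139). ENSRNOG00000003357 was the single gene called lower, with 1760 ± 193 CPM in young and 880 ± 110 CPM in old controls, a log2 fold change of -1.0 (SE 0.16, 95% interval -1.34 to -0.67, edgeR adjusted p = 0.0139). For each of these 3 IDs, all 4 old control libraries lay on one side of all 4 young control libraries. The counts behind these values ranged from 43 to 17296 per library. Each of the 3 calls was lost without young control replicate 1, with edgeR adjusted p-values of 0.0784, 0.0718 and 0.0718. The call of ENSRNOG00000021027 was also lost without young control replicate 2 (0.105), young control replicate 3 (0.117) or old SVF-treated replicate 2 (0.0638), and that of ENSRNOG00000003357 without old control replicate 2 (0.0506). With no filter on low counts ENSRNOG00000021027 was not called (0.104), and with 2 surrogate variables ENSRNOG00000030729 was not called (0.0890).

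The effect of SVF cells in old rats was addressed by comparing old SVF-treated with old control. No gene was called: 0 of 12496 by edgeR's quasi-likelihood test, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 there were 367 genes, fewer than the 625 that chance gives. DESeq2 called 0 genes, with 496 at an unadjusted p under 0.05, and limma voom with sample quality weights called 0, with 577. The median 95% interval reached 0.58 to either side of the log2 fold change, and 0.34 for genes above 64 CPM. In simulated data at this depth and spread, 43.6% of genes changed 2-fold and 72.0% of genes changed 4-fold were recovered when 200 genes changed. Of genes changed 1.5-fold, 5.20% were recovered. The simulation treats genes as independent and holds no library that stands apart from the others, so recovery in the real libraries may differ.

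Of the 4 IDs, ENSRNOG00000021027 differed most between these groups, with 110 ± 54.8 CPM in old controls and 47.5 ± 24.3 CPM in SVF-treated rats (SD, n = 4). Its log2 fold change was -1.21 (SE 0.37, 95% interval -1.99 to -0.43), which did not pass the correction (edgeR adjusted p = 0.999), and the libraries of the groups overlapped. ENSRNOG00000030729 changed by -0.26 on the log2 scale (95% interval -0.79 to 0.26) and ENSRNOG00000003357 by 0.18 (95% interval -0.15 to 0.51). ENSRNOG00000000885 changed by -0.57 (SE 0.27, 95% interval -1.14 to 0), away from the young level, and did not pass the correction either (edgeR adjusted p = 0.999). ENSRNOG00000000885 was chosen by its fall in SVF-treated rats, and the other IDs by their change in old controls. The choice reuses the same libraries and by itself favours the direction of each change given here. The intervals do not allow for that.

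Old SVF-treated rats were also compared with young control rats. These groups differ in both age and treatment, so a gene called here need not be an age difference that remained after treatment. Here 8 genes were called by edgeR, 6 higher and 2 lower in SVF-treated rats. At an unadjusted p under 0.05 there were 889 genes, and chance gives 625. DESeq2 called 56 genes and limma voom with sample quality weights called 33, while edgeR with only the 2 groups compared called 3, of which 2 were among the 8. The smallest adjusted p was 0.0462, close to the threshold, so that the count moved with small changes. It was 0 without any 1 of young control replicates 2, 3 and 4, old control replicates 2 and 3, and old SVF-treated replicates 1, 3 and 4. It was 22 without old control replicate 1, 13 without old control replicate 4 and 21 without old SVF-treated replicate 2. The old controls enter this comparison only through the shared estimate of the spread, the scaling and the filter.

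ENSRNOG00000030729 was at 57.6 ± 6.13 CPM in SVF-treated rats and 21.0 ± 9.28 CPM in young controls (SD, n = 4), a log2 fold change of 1.46 (SE 0.26, 95% interval 0.91 to 2.00, edgeR adjusted p = 0.0462). ENSRNOG00000000885 had the deepest fall, from 42.6 ± 13.4 CPM in young controls to 15.4 ± 3.44 CPM in SVF-treated rats, with 22.8 ± 6.50 CPM in old controls. Its log2 fold change from young was -1.46 in SVF-treated rats (SE 0.28, 95% interval -2.04 to -0.89, edgeR adjusted p = 0.0462) and -0.90 in old controls (SE 0.27, edgeR adjusted p = 0.535). In all 4 SVF-treated libraries it lay below all 4 young libraries. Both calls were lost without any 1 of the 4 young control libraries, old control replicates 2 and 3, and old SVF-treated replicates 1, 3 and 4, with edgeR adjusted p-values between 0.0527 and 0.232. Both were also lost with only the 2 groups compared (0.0547 and 0.0536) and with 2 surrogate variables (0.150 and 0.130). ENSRNOG00000021027 and ENSRNOG00000003357 did not pass in this comparison, with log2 fold changes of 1.52 and -0.82 and edgeR adjusted p-values of 0.248 and 0.0522. DESeq2 called both (adjusted p = 0.0176 and 0.000156). ENSRNOG00000003357 was also called with no filter on low counts (0.0247), by limma voom with sample quality weights (0.0176), without old control replicate 1 (0.0201), without the 2 libraries of lowest correlation (0.0485) and at a threshold of 0.1.

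**Figure D3:**
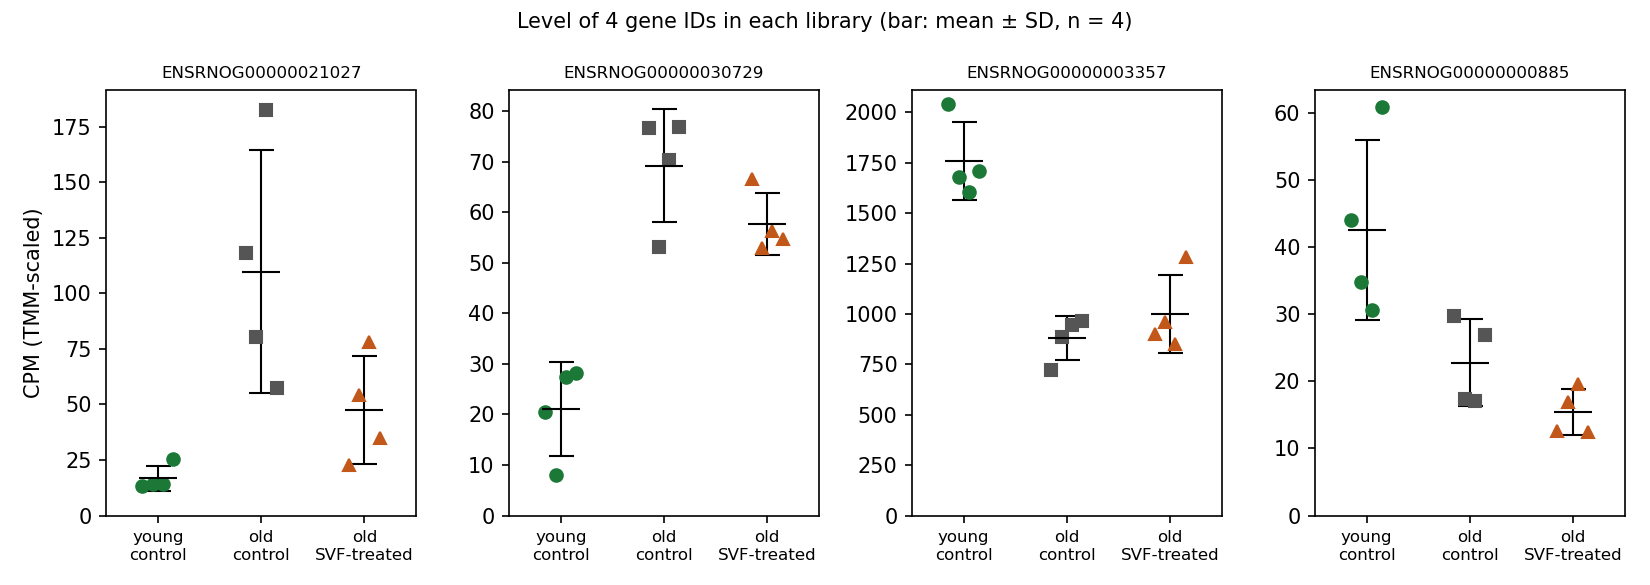
TMM-scaled CPM (y axis, from 0) of 4 gene IDs in each library of the 3 groups (x axis), with 1 point per library and bars for the mean ± SD of 4 libraries. ENSRNOG00000030729 lies at 53.0 CPM or more in all 8 old libraries and at 28.2 CPM or less in the young ones, and the SVF-treated and old control libraries overlap for all 4 IDs.

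The gene calls of the 2 comparisons against young controls overlapped in 3 genes, all of them higher in both. Independent lists of these sizes share 0.0019 genes in that direction, but these lists are not independent, as both use the young controls. Simulated libraries with no effect, which share the young controls, shared 0.01 genes on average and 1 at most over 100 sets. These sets called only 0.14 genes in old control and 0.15 in old SVF-treated rats on average, so they could hardly share more. Neither value shows what overlap chance gives for lists as long as the real ones. With the young controls split so that each comparison kept 2 of them, 0 genes were shared in any of the 6 splits, with at most 1 gene called in old control and 8 in old SVF-treated rats. The split also left fewer young libraries to each comparison.

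Whether SVF treatment opposed the age-related change was examined over all genes, as the covariance of the log2 fold changes old minus young and SVF-treated minus old. Both use the old controls, so the covariance is negative with no effect at all. It was -0.0877 (r = -0.407 across genes, which are not independent replicates), and simulated libraries with no effect gave -0.125 (r = -0.499). The difference, 0.0376, was farther from 0 than in any of 100 simulated sets. The simulation gives all groups the same spread and treats genes as independent. With the old controls split so that no library entered both fold changes, the covariance was 0.0139. Relabelling old control and SVF-treated libraries gave -0.0311 to 0.0305 (exact permutation test over 70 relabelings, 2-sided p = 0.4). Neither the difference from the simulated libraries nor the covariance with split controls was negative.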

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

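Of the tests in this part, those of the exchange of 2 libraries, and the comparison of the 8 old libraries with young control, were chosen only after the data were seen.

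One value stood apart from its group. ENSRNOG00000021027 was at 25.4 CPM in young control replicate 4, while the other 3 young libraries lay between 13.1 and 14.3 CPM. The gap to the nearest library was 0.900 of the group's range, above Dixon's 95% limit for 4 values. Such a limit is passed by chance in about 1 of 20 groups, and 33 groups of values were examined. All 4 old control libraries lay above it, at 57.4 CPM or more.

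Other splits of the same libraries were used to ask whether chance can be excluded for each count of genes. For old control against young control, 2 of 35 splits called as many genes as the real 5, so chance cannot be excluded, and the highest other split called 86. For old SVF-treated against old control the real count is 0, so all 35 of 35 splits call at least as many whatever the data, and the splits say nothing about chance. The highest other called 1. For old SVF-treated against young control, 1 of 35 splits, the real one, called 8, and the highest other called 1. That is the lowest share that 35 splits can give, with no correction for the several counts tested. These splits therefore argue against chance but do not exclude it. For the 8 old libraries against young control, fitted as 2 groups, the real split called 13. It was the 1 of 100 splits drawn that called as many, with a highest other of 2. The draw took only some of the possible splits. It did not include the exchange of young control replicate 3 and old control replicate 1, the split that called 86 genes above. Whether that split would call more than 13 here is therefore not known, and chance is not excluded.

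The split that called 86 genes exchanged young control replicate 3 and old control replicate 1. None of the 86 was among the 5 genes called with the real labels (0 shared), and 28 had an unadjusted p under 0.05 there. A split that calls several times the real count points to a structure of the samples. Swapped labels could give it. With both libraries left out, 428 genes differed between the other 7 old and 3 young libraries at an unadjusted p under 0.01, and each library was placed on the axis from young (0) to old (1). Old control replicate 1 lay at 0.479 and young control replicate 3 at 0.587, a difference of -0.108, while the 15 other pairs of a young and an old control gave 0.120 to 0.749. Yet young control replicate 3 did not reach the range of the other left-out old controls, 0.677 to 1.00. It lay just above that of the other left-out young controls, 0.101 to 0.558. Both ranges leave out these 2 libraries. Paired with other libraries, old control replicate 1 lay at 0.564 to 0.640 and young control replicate 3 at 0.529 to 0.583. Each pair has its own set of genes, so positions of different pairs compare only roughly. Of the 428 genes, 223 had both libraries on the side opposite to their labels and 65 on the labelled side. The other pairs, with only 146 to 303 genes, gave 8 to 50 and 63 to 95. As a share of its genes, the labelled side was lowest in the exchanged pair. The pair was chosen for its many calls, which favours this outcome. The 3 IDs named as called in old control against young control run as labelled: old control replicate 1 was at 118, 76.7 and 723 CPM and young control replicate 3 at 14.3, 27.3 and 1607 CPM for ENSRNOG00000021027, ENSRNOG00000030729 and ENSRNOG00000003357. These were chosen with the labels as given, which favours that outcome in turn. ENSRNOG00000000885, chosen in another comparison, does not separate them: young control replicate 3 was the lowest young library at 30.7 CPM and old control replicate 1 the highest old control at 29.7 CPM. Genes that vary together between libraries within groups could also give it: in the SVF-treated libraries, which the exchange does not move, the mean correlation of the 86 genes was 0.0117, at percentile 88.1 of 1000 random lists of like abundance. The tables leave both explanations open, and swapped labels cannot be told apart from 2 libraries that lie between the groups.

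The genes missing from single libraries form a pattern of their own. Over the 12 libraries, 437 times a gene had a count of 0 in one library and at least 20 in each of the 3 other libraries of its group, for 418 distinct genes. Old SVF-treated replicate 2 lacked 149, old control replicate 4 lacked 84, old control replicate 2 lacked 67 and old SVF-treated replicate 4 lacked 63. Sequencing depth is argued against: Poisson sampling at each library's depth gives 9.6e-06% of the observed number. A single cell type missing from the pooled vessels would make its genes vary together in the other libraries. In 0 of the 4 libraries with at least 50 such genes did they correlate above the upper 95% limit of 1000 random lists of like abundance, with mean correlations of 0.00832 to 0.0411. The same value, 0 of 4, is what few starting RNA molecules predict, but any cause that strikes genes independently gives it too. Loss of molecules before amplification is thus possible but not shown. Whether this test could detect a missing cell type was not checked. Age or treatment stays open. The number of such genes per library averaged 13 ± 13.4 in young controls, 38.3 ± 43.6 in old controls and 58.0 ± 65.9 in old SVF-treated rats (SD, n = 4; exact permutation p = 0.443 over the 3 groups, a test added after the values were seen). The number of all tested genes at 0 gave an exact permutation p of 0.877. Neither shows that the groups are equal.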

How the results depend on the processing

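Surrogate variables, leaving out the 2 libraries that stand apart, and pooling the 8 old libraries were chosen after the data were seen. The cause of a change was not tested unless one is given.

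For old SVF-treated against old control, 0 genes were called under each of the 24 alternatives run with edgeR, DESeq2 or limma. For old control against young control (5 genes), DESeq2 gave 23, voom with quality weights 17, a threshold of 0.1 gave 8, a test against a log2 fold change of 0.5 gave 0, and the 8 old libraries pooled gave 14. The DESeq2 and voom lists held all 5 genes. For old SVF-treated against young control (8 genes), DESeq2 gave 56, voom 33, no filter 15, only the 2 groups compared 3, a threshold of 0.1 gave 25, a log2 fold change of 0.5 gave 0, the 2 apart libraries left out gave 32, and the 8 old libraries pooled gave 14. The DESeq2, voom and unfiltered lists held all 8. RLE factors, library totals alone and a mean CPM of at least 5 kept both counts within 1.5 times. With surrogate variables the counts were 7 and 8 but the genes changed: 3 of the 5 and 2 of the 8 remained, and 3 were higher and 4 lower in the first, 4 and 4 in the second.

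Leaving out each library gave 0 to 12 genes for old control against young control, 0 to 0 for old SVF-treated against old control, and 0 to 22 for old SVF-treated against young control.

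Replicate numbers did not pair the libraries: correlations of same-numbered deviations were -0.006 to 0.090 in 12 pairs, and 5 of 12 libraries correlated best with their own number. With the replicate number as a block, 7, 0 and 2 genes were called in the 3 comparisons, and ENSRNOG00000000885 was not called against young control (edgeR adjusted p = 0.0793).

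The covariance difference of 0.0376 kept its sign in the other settings that use simulated libraries. Its simulation p was 0.0099 in each setting, the lowest that 100 sets can give. Because the simulation treats genes as independent, this p may overstate the evidence, and its repetition adds none. The covariance with split controls, which needs no simulated value and has another test, was also positive, 0.0139, but did not pass (exact permutation p = 0.4). The difference was 0.0119 at a mean CPM of at least 5 and 0.0213 with the replicate block, and 0.0209 to 0.0606 with a library left out.

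The fold changes of the 4 IDs kept their sign under all 24 alternatives in all 3 comparisons. Of these 288 values, 244 kept their side of the threshold, 37 were no longer called and 7 became called. Most of the 244 belong to results that were not called in the main analysis and had no call to lose. In old SVF-treated against young control, ENSRNOG00000030729 lost its call in 12 of 24 alternatives and ENSRNOG00000000885 in 13. In old control against young control, ENSRNOG00000021027 lost its call in 6 of 24, and ENSRNOG00000030729 and ENSRNOG00000003357 in 3 each. As a mark of depth, 3 counts correspond to 0.277 to 0.738 CPM in these libraries. The 4 IDs lay well above this, with at least 43 counts in every library, and whether depth moved their calls was not tested. The gene list, marker and cardiomyocyte alternatives were not run, since the IDs are not paired with symbols.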

Other observations

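The tests in this part were chosen after the result was seen.

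With the 8 old libraries pooled, 14 genes were called against young control by edgeR, 7 higher and 7 lower, with 35 at an adjusted p under 0.1. All 14 had the same sign in both old groups. Of these genes 5 were called in old control against young control and 7 in old SVF-treated against young control. The contrast favours genes that move alike in both old groups, so this list cannot show a return toward the young level.

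A full return of age-shifted genes to the young level after SVF was tested as a hypothesis on all 12496 genes. It needs a covariance, with split old controls, near minus the variance of the age effect. That variance, from parts of each group that share no library, was 0.0433, and the covariance was 0.0139. This covariance was the highest of the 35 relabelings of young and SVF-treated libraries, with 0.0099 as the next. That is the lowest share this test can give, and the variance of 0.0433 is itself an estimate whose error was not measured. Over all tested genes the tables thus argue only weakly against a full return. For the 3031 genes with a mean log2 CPM above 6 the covariance was 0.0108, and 2 of 35 relabelings were as high. Their age-effect variance was 0.00999, and relabelling old control and SVF-treated libraries gave -0.0230 to 0.0170, so for these abundant genes a full return is not excluded. The covariance of the 2 changes from young, with the young controls split, was 0.0572. The variance of SVF-treated minus old, computed in the same way, was -0.0194, below what any real effect gives, and so no effect of SVF could be measured over all genes. A partial return, or a return of few genes, may have gone unseen.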
